A study of Homo sapiens with 3 samples.

How the data were processed

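Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HepG2, a human hepatocellular carcinoma cell line, with 3 antibodies. One antibody was raised against the F domain of HNF4alpha (the C-terminal domain of this nuclear receptor), one against its AB domain (the N-terminal activation domain), and one against HNF4gamma, its paralog. There was 1 library per antibody and no input library among the samples analysed here. Per the labels' protocols, sonicated nuclei were precipitated, the DNA was amplified by PCR after adapter ligation, and fragments were isolated from a gel and read on an Illumina Genome Analyzer. The aligner, the program that made the scores and the genome build are not given in the sources used here.

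Each deposited table has 3 columns without a header, which hold a chromosome, a position and a score made by the authors. The meaning of the score was worked out from its values. Up to a window count of 25 reads, the deposited scores equal the negative log10 of the Poisson probability of at least that many reads, with 1 expected count per library and errors of at most 0.00186. From 26 reads on, the score is the count times a constant, so every score could be turned back into a number of reads per window. Only windows with a Poisson probability of at most about 0.001 are listed, which is a count of at least 8 reads in the F and AB libraries and 7 reads in the HNF4gamma library. The expected count was 1.57 reads per window for F, 1.56 for AB and 1.45 for HNF4gamma, so the HNF4gamma library had 92.4% of the depth of F if the windows and the genome constant were the same. A regression of the count on the listed positions around it gave 1.31 (F) and 1.34 (AB) reads per listed position within 140 bp, and -0.0326 and -0.0145 beyond 180 bp. A window of 300 bp centred on the listed position was therefore used. It could not be fitted in the HNF4gamma library, which has too few high windows, and was assumed to be the same there.

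Above 25 reads, counts that were not whole within a tolerance of 0.01 were read as windows with reads shared between several places in the genome. Such windows made up 41.8% of positions over 25 reads in F, 51.8% in AB and 97.5% in HNF4gamma. Regions with a summit within 1000 bp of such a window in any library were left out. Below 26 reads the authors' scores carry no fraction, so shared reads cannot be recognised there away from higher windows.

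On chromosomes 2 to 22, positions lay past the chromosome's end on 17 of 21 chromosomes in NCBI36 and 11 of 21 in GRCh38, and on 0 of 21 in GRCh37. Coordinates are given as the tables list them. Chromosomes 1, X and Y hold positions past their ends or long empty stretches and entered no comparison between libraries, nor did mitochondrial sequence. A genome sequence and annotation of the matching build were not used here, so regions are named by position, and the planned analyses of annotation, gene lists and sequence motifs were not run.

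Enriched regions were called per library from windows that passed a Poisson test against the library's own expected count, with Benjamini-Hochberg adjustment at 1e-05 over all windows with reads. This came to 12 reads per window in each library. The adjustment counted windows near shared reads, which were left out only afterwards. They held 61.8% of the listed positions in HNF4gamma, so the cut there may be too lax for the windows kept. Passing positions within 200 bp were merged, and at least 8 listed positions were required in the window around the summit. The planned local background, strand and duplicate filters, and 200 bp windows, could not be applied to scores, and the authors' windows and a genome-wide rate took their place. Regions of 2 libraries were counted as shared when their summits lay within 200 bp. Shares have exact 95% binomial intervals. Those of shared regions were set beside 100 random shifts along each chromosome. Shares of regions listed in another library, by class of reads, were set beside fewer such shifts. Shares of listed positions have Wilson intervals, which treat positions as independent although neighbouring windows share reads, so they are too narrow.

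Regions of all libraries were merged, and the highest window count of each library in each region was compared by a two-sided exact conditional binomial test, scaled by the total reads in merged regions. A difference was called at an adjusted p of at most 0.05 (Benjamini-Hochberg) with a ratio of at least 2. Where a region was not listed in a library, the count just below its listing threshold (7 or 6 reads) stood in as an upper bound, and no call was made in that library's favour. Ratios against such a region are lower bounds before scaling. The test compares reads of 2 libraries, not the antibodies or proteins, and all intervals cover counting error only, since PCR copies are not independent molecules. The rule for named regions, fixed before the data were examined together with the tests and most alternatives, takes the 10 merged regions with the most reads over the 3 libraries. Per pair of libraries and direction it adds the 5 called regions with the largest ratio among those with at least 20 reads in the higher library.

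On simulated data the decoding returned 100% of counts. The simulated scores were written with the rule that the decoding assumes, so this checks the code and not the rule. The simulated background was spread evenly at 1 genome-wide rate. Chance then gave 8 called regions in the F, 5 in the AB and 3 in the HNF4gamma simulation. The background of the data was uneven, so these numbers are not estimates of false calls in the data. Simulated sites at 10 times the background were recovered in 86.2%, 88.2% and 82.7% of cases, and at 5 times in 10.5%, 16.4% and 7.39%. By chance alone, with an even background, 18423 regions reached the listing threshold in the HNF4gamma simulation. The library itself had 16949 listed regions, so a listed HNF4gamma position is not by itself a sign of binding. Listed positions at HNF4alpha regions were set beside shifted places, and those away from them were used as a measure of background. For the difference test between F and AB, run on 16604 regions, 4-fold changes were recovered in 44.0% of all changed regions and 97.2% of those with a mean over 25 reads, with 1 unchanged region called. For 2-fold changes the recovery was 2.5% and 12.5%.

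Alternatives covered the threshold, depth by thinning of counts, the definition of a shared region, the scaling and a filter on low counts. Keeping regions with shared reads, and adding chromosomes 1, X and Y, were chosen after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.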

Results

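The data collected were genome-wide binding maps of HNF4alpha, a nuclear receptor central to hepatocyte gene expression, and of its paralog HNF4gamma in HepG2 cells. The design compared 2 antibodies directed at different domains of HNF4alpha, F and AB, and set HNF4gamma beside them. Each antibody had 1 library, so differences have no replicate check. The tables listed 819758 positions for F, 657009 for AB and 342005 for HNF4gamma, of which 646045, 497748 and 217867 lay on chromosomes 2 to 22. The expected background was 1.57, 1.56 and 1.45 reads per 300 bp window.

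Enriched regions were found at many places with both HNF4alpha antibodies. Without an input library, binding there was not separated from background that is high in every library. At 12 or more reads per window, 14702 regions were called with the F antibody and 10755 with the AB antibody, against 745 with the HNF4gamma antibody. The median region held 18 reads with either HNF4alpha antibody, 11.5 (F) and 11.6 (AB) times the background, and was 202 and 189 bp wide between its outermost passing positions. HNF4gamma regions were weaker, with a median of 14 reads and a width of 146 bp. Over 25 reads were reached by 4170 F regions, 2697 AB regions and 6 HNF4gamma regions, and at least 50 reads by 1217, 650 and 1. Own regions held 50.3% of the listed positions in F (Wilson 95% interval 50.2 to 50.4), 43.5% in AB (43.3 to 43.6) and 6.08% in HNF4gamma (5.98 to 6.18). Places near reads shared between several genome positions held 28.5% of the listed positions in F, 34.8% in AB and 61.8% in HNF4gamma, and removing them took away 43.4% of the HNF4gamma regions. The HNF4gamma count rested on the threshold, with 1981 regions at an adjusted p of 0.01 and 221 at 1e-10.

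The region with the most reads was on chromosome 21, positions 16512730 to 16513197. Its highest window held 478 reads with F (exact 95% interval 436 to 523) and 442 with AB (402 to 485). With HNF4gamma it held 22 (13.8 to 33.3). These were 304, 284 and 15.2 times the background of each library. The next was chromosome 5, positions 149922501 to 149923003, with 458 (417 to 502), 375 (338 to 415) and 51 reads (38.0 to 67.1), which was the highest HNF4gamma count among called regions. Chromosome 17, positions 26695113 to 26695687, held 290 reads with F, 283 with AB and 20 with HNF4gamma. Chromosome 14, positions 39735530 to 39736554, held 263, 220 and 24 reads, and chromosome 10, positions 135191900 to 135192424, held 256, 232 and 15. The remaining places among the 10 with the most reads were chromosome 6 at 168076696 to 168077233 (267, 195 and 35 reads in F, AB and HNF4gamma), chromosome 21 at 40757308 to 40757985 (246, 216 and 27), chromosome 22 at 18631159 to 18631610 (256, 201 and 21), chromosome 9 at 90183899 to 90184502 (248, 195 and 11) and chromosome 2 at 238499062 to 238499564 (196, 191 and 16). All 10 were listed in all 3 libraries.

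**Figure D1:**
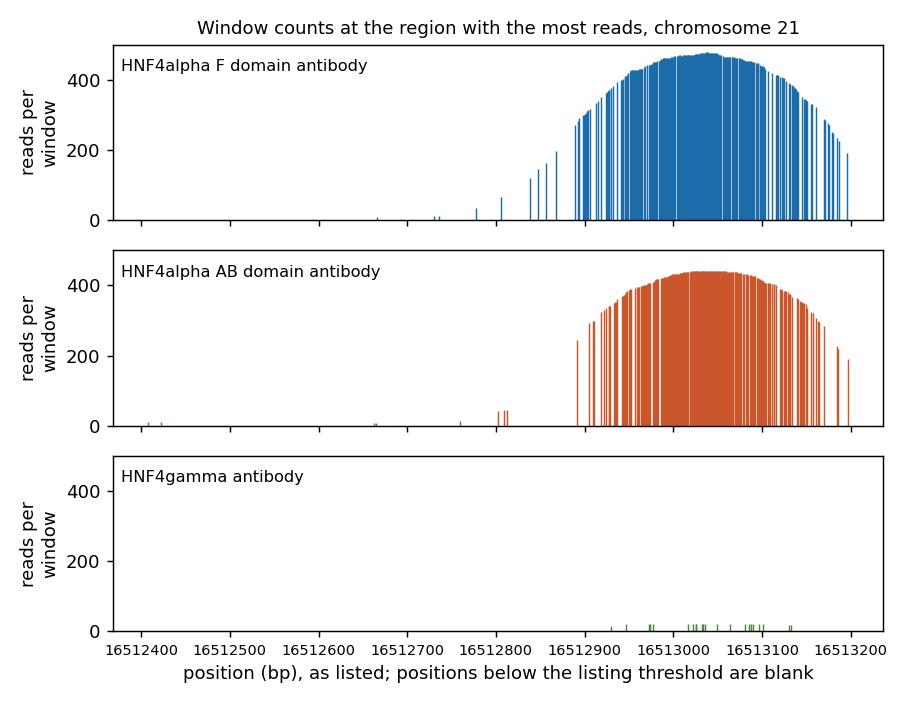
Reads per 300 bp window (y axis, linear from 0) at each listed position (x axis, bp) of the region with the most reads, on chromosome 21, in the F, AB and HNF4gamma libraries from top to bottom. Each vertical line is 1 listed position, and the highest lines reach 478, 442 and 22 reads.

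The first comparison asked whether antibodies to different domains of HNF4alpha find the same binding sites. Of the 10755 AB regions, 9064 (84.3%, exact 95% interval 83.6 to 85.0) had an F summit within 200 bp, against a mean of 0.26% after random shifts. Of the 14702 F regions, 61.7% (60.9 to 62.4) had an AB summit, against 0.187%. The median distance between shared summits was 34 bp. Agreement rose with the number of reads. F regions of 12 to 15 reads were called with AB in 28.4% of cases (27.2 to 29.7), those of 16 to 25 reads in 66.6% (65.3 to 67.9), those of 26 to 39 reads in 95.3% (94.3 to 96.1) and those of 40 to 74 reads in 99.7% (99.2 to 99.9). All 1467 F regions of 40 to 74 reads and all 450 of 75 or more were listed in AB at a Poisson probability of at most 0.001. The F regions that had no AB call in the same merged region numbered 5732, with a median of 14 reads, and 48.8% of them (47.5 to 50.1) were still listed in the AB library. Only 96 of them had over 25 reads. The converse class numbered 1743, of which 2 had over 25 reads.

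No region passed the test of a difference between the F and AB libraries. Of 16604 merged regions, 0 passed the exact conditional binomial test (adjusted p at most 0.05) with a ratio of at least 2 in either direction. In the same test 586 had an unadjusted p under 0.05. That is a smaller share than the 0.05 chance would give, so it is not by itself a sign of differences. Scaled by background depth in place of reads in regions, 14 regions were higher in F and 0 in AB. With regions of shared reads kept, a setting chosen after seeing the data, 2 were higher in F and 19 in AB. The scale from reads in regions was 1.29 for F over AB, with unlisted regions at their bound of 7 reads (3041 in AB and 889 in F), and the median ratio was 1.36, while the background differed by a factor of 1.01. Across the 12762 regions listed in both libraries, the log2 counts correlated with a Pearson r of 0.815 and a Spearman rho of 0.709, where regions are not independent replicates. In simulated data the test recovered 44.0% of 4-fold and 2.5% of 2-fold changes over all regions, and 97.2% and 12.5% of those at over 25 reads. At weaker regions many differences of 4-fold were thus not detectable at this depth. Differences of 2-fold were rarely called, in part because the observed ratio itself had to reach 2, which more depth would not change.

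**Figure D2:**
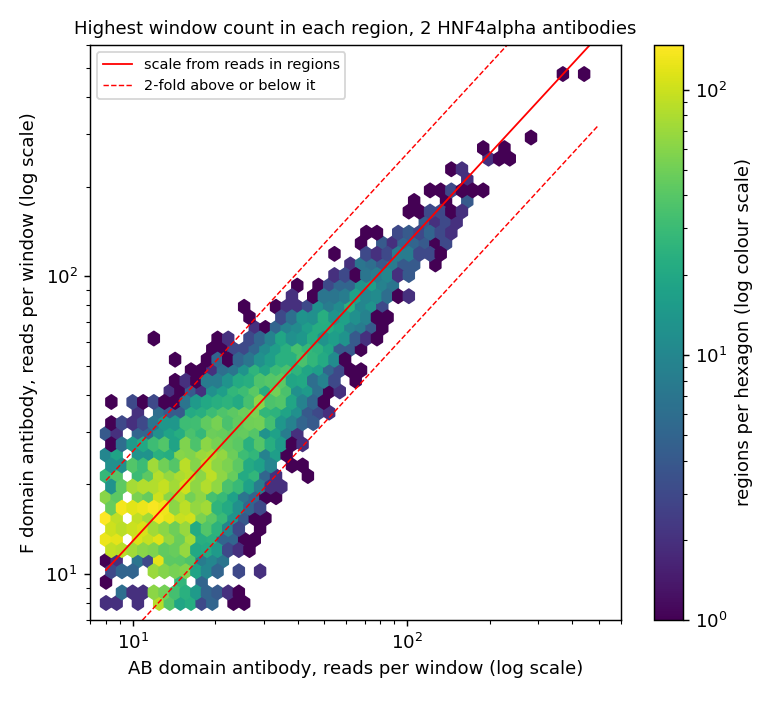
Highest window count (reads, log axes) in each of the 12762 merged regions listed with both HNF4alpha antibodies, AB on the x axis and F on the y axis, coloured by the number of regions per hexagon on a log scale. The solid line is the scale from reads in all merged regions (1.29), unlisted ones at their bound, and the dashed lines lie 2-fold above and below it. Counts below 8 reads are not listed.

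The second comparison asked where HNF4gamma is bound relative to HNF4alpha. Of the 745 HNF4gamma regions, 499 (67.0%, 63.5 to 70.4) shared a summit with F and 495 (66.4%, 62.9 to 69.8) with AB, against 0.26% and 0.195% after random shifts. These fell into separate kinds of place. At strong HNF4alpha regions, 208 HNF4gamma regions lay on F regions of at least 40 reads, with a median of 14 HNF4gamma and 88 F reads. A further 348 lay on HNF4alpha regions under 26 reads, with a median of 16 HNF4gamma and 15 F reads, and 86.8% of these (82.8 to 90.2) had another HNF4gamma region within 100 kb. The same crowding was found for 19.2% (14.1 to 25.3) of the regions at F regions of at least 40 reads. Another 170 lay at no called HNF4alpha region, and 72.9% of these (65.6 to 79.5) were crowded in this way. The remaining regions were 15 at F regions of 26 to 39 reads, of which 3 were crowded, and 4 others.

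HNF4alpha regions with more reads were listed more often in the HNF4gamma library. The share of F regions listed in the HNF4gamma library was 8.16% (7.43 to 8.93) at 12 to 15 F reads, 10.5% (9.71 to 11.4) at 16 to 25, 16.96% (15.4 to 18.6) at 26 to 39, 37.7% (35.2 to 40.2) at 40 to 74 and 73.6% (69.2 to 77.6) at 75 or more. Shifted regions were listed in at most 0.641% of cases. Where listed, the median HNF4gamma count was 10, 8, 8, 8 and 11 reads in these classes. At the 189 F regions of at least 100 reads, F and HNF4gamma counts had a Spearman rho of 0.41, with 34 unlisted regions at their bound of 6 reads. Over all merged regions listed in both libraries, crowded weak places included, the log2 counts had a Pearson r of -0.0623 and a Spearman rho of -0.077 for F (2214 regions) and 0.0247 and -0.00679 for AB (2178 regions), where regions are not independent replicates. The AB regions gave the same order, from 10.6% (9.65 to 11.5) at 12 to 15 reads to 82.0% (76.4 to 86.8) at 75 or more. The stricter calling of HNF4gamma regions did not rise evenly. It was 2.53% (2.12 to 2.99) at F regions of 12 to 15 reads, 0.666% (0.373 to 1.10) at 26 to 39 and 29.6% (25.4 to 34.0) at 75 or more.

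**Figure D3:**
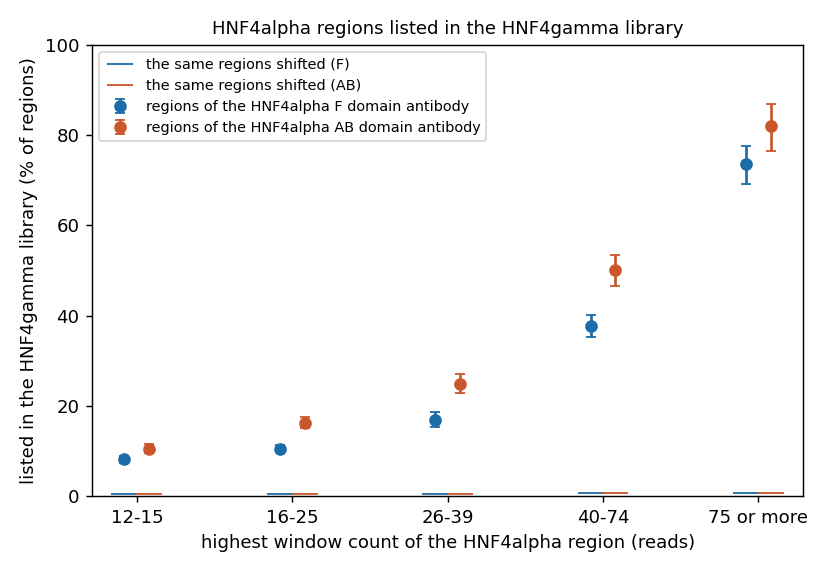
Share of F (blue) and AB (orange) regions listed in the HNF4gamma library (y axis, percent) by the highest window count of the region (x axis, reads). Points carry exact 95% binomial intervals, and horizontal dashes are the mean of the same regions at randomly shifted places. For F the share goes from 8.16% to 73.6%.

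Among the 16604 merged regions, 397 were called higher in F than in HNF4gamma and 437 higher in HNF4gamma by the exact conditional binomial test, after scaling by reads in regions. For AB and HNF4gamma the numbers were 333 and 172. This split rested on the scaling and on the regions with few reads. With the background depth as the scale, 6423 regions were higher in F and 1 in HNF4gamma, and 3791 were higher in AB and 2 in HNF4gamma. With the median ratio the numbers were 953 and 300, and 671 and 67. With only regions of at least 20 reads over the pair, 228 were higher in F and 416 in HNF4gamma. For AB the order turned, with 159 higher in AB and 373 in HNF4gamma. HNF4gamma was unlisted in 14238 of the regions, which enter the scaling at their upper bound.

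Places with the largest excess of F over HNF4gamma included chromosome 3 at 133449754 to 133450247, with 154 F, 118 AB and at most 6 HNF4gamma reads, a scaled ratio at that bound of 7.36 (exact 95% interval 3.30 to 20.4), or 23.7 with the background depth as the scale. Chromosome 2 at 235597733 to 235598199 held 192 F and 8 HNF4gamma reads (ratio 6.88, 3.42 to 16.2, or 22.2 with the background depth). Chromosome 2 at 169334769 to 169335181, chromosome 18 at 33756107 to 33756527 and chromosome 9 at 107662043 to 107662497 held 143, 140 and 137 F reads and at most 6 HNF4gamma reads each. Against AB, the rule named the place with the most reads, chromosome 21 at 16512730 to 16513197 (7.43, 4.85 to 11.98, or 18.8 with the background depth). It also named chromosome 4 at 140610539 to 140610889 with 120 AB reads and chromosome 7 at 73037170 to 73037855 with 119, both with at most 6 HNF4gamma reads, and the places given above on chromosomes 3 and 9. Ratios at places with at most 6 HNF4gamma reads are taken at that bound, so their rank among the named places is not settled.

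The places named for a scaled excess of HNF4gamma held 20 to 26 HNF4gamma reads, where the rule asks for at least 20. Chromosome 2 at 91812422 to 91812699 held 21 HNF4gamma reads and at most 7 with F or AB, a scaled ratio over F at that bound of 10.5 (4.29 to 29.1), which is 3.25 with the background depth as the scale. Chromosome 21 at 10778960 to 10779300 held 20 HNF4gamma, 9 F and 22 AB reads, and at 10783203 to 10783588 it held 24, 13 and 10. Chromosome 10 at 47059097 to 47059691 held 20, 10 and 12 reads and chromosome 20 at 29813725 to 29814037 held 20, 11 and 14. Against AB, the rule added chromosome 9 at 141054268 to 141054497 (23 HNF4gamma, 24 F and 8 AB reads), chromosome 21 at 9833877 to 9834316 (26, 18 and 12) and chromosome 2 at 89860410 to 89860656 (22, 16 and 11). With the background depth as the scale, ratios over F at the later places named against F were 1.97 to 2.41. Those over AB at the added places were 2.14 to 3.08. The places at 10778960 and 10783203 lie in a megabase of chromosome 21 with 28 regions called with both HNF4alpha antibodies. Its highest F count was 23 reads, and 27 of these regions were listed in HNF4gamma.

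HNF4alpha regions were spread unevenly over the chromosomes, with closely correlated densities for the 2 antibodies. F regions per Mb ranged from 2.51 on chromosome 13 to 13.3 on chromosome 17, and AB regions from 1.80 to 9.69 on the same chromosomes. Lengths ran to the last listed position, empty stretches included. Chromosomes such as 13 and 14 were hardly listed below 20 Mb, which lowers their values per Mb, so their rank is not settled. Over 21 chromosomes the 2 densities correlated with a Pearson r of 0.994 and a Spearman rho of 0.991 (permutation p = 1e-05 for both, the smallest the permutations can give, adjusted p = 3e-05 over 3 relations), and with r = 0.990 without chromosomes 17 and 20. The weak positions of the HNF4gamma library away from called HNF4alpha regions were also uneven. They formed 13.02 regions per Mb on chromosome 20, 11.9 on chromosome 14, 10.5 on chromosome 2, 10.4 on chromosome 17 and 9.24 on chromosome 16, against 1.57 on chromosome 13. Their density correlated with that of F regions (Pearson r = 0.656, permutation p = 0.00139, adjusted p = 0.00151; Spearman rho = 0.666, permutation p = 0.00132, adjusted p = 0.00198), with r = 0.781 without chromosomes 14 and 20.

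**Figure D4:**
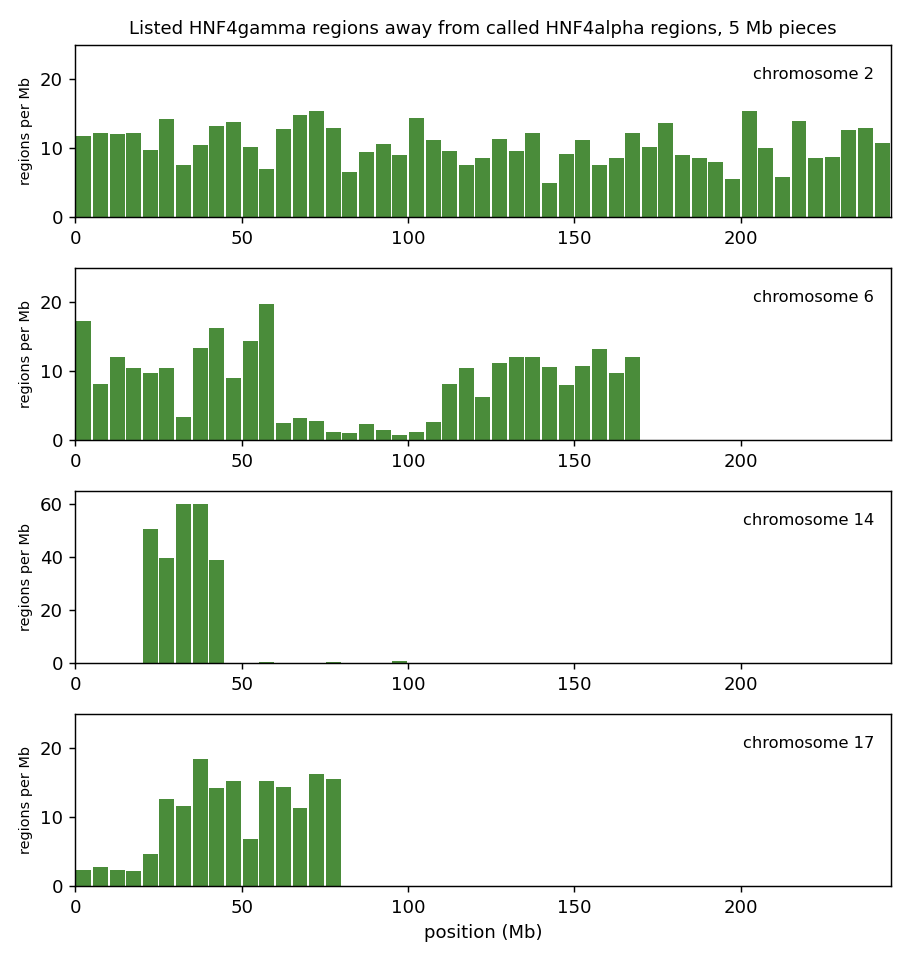
Listed HNF4gamma regions more than 1000 bp from called HNF4alpha regions, per Mb in pieces of 5 Mb (y axis, from 0, with a taller range for chromosome 14), along chromosomes 2, 6, 14 and 17 (x axis, Mb). Chromosome 14 goes from 49.8 regions per Mb between 20 and 45 Mb to 0.21 above 45 Mb, and chromosomes 6 and 17 also change in steps.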

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

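The following values lie outside the chromosomes compared in the report, and none of them has a control sample. The test of chromosome X below was chosen after its result was seen. Mitochondrial windows held a median of 426 reads in F, 952 in AB and 547 in HNF4gamma, far above the background of under 2 reads per window. The first 0.3 Mb of chromosome 1 held 80743 listed positions in F, 80970 in AB and 80718 in HNF4gamma, and 2.06% of the counts over 25 reads there were whole in F.

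Chromosome X beyond 84 Mb held 23667 listed positions in F, against 2577 below 58 Mb, and the positions ran to 167 Mb, past the end of that chromosome. Chromosome 1 had no position between 4.60 and 151 Mb in F, and chromosome Y was listed to 67.1 Mb, also past its end, with an empty stretch of 21.1 Mb in all 3 libraries. A candidate explanation is that most of chromosome 1 is listed under X and Y in these tables. F regions over 25 reads were 9.42 times as dense on X above 84 Mb as below 58 Mb (2.92 against 0.31 per Mb), which goes with it. The length set for the test does not settle it, as the stretches past 84 Mb on X and past 30 Mb on Y add up to 119 Mb, against 146 Mb missing on chromosome 1 in F. Counted from the start of Y, a choice made later, the sum is 149 Mb. The explanation stays open. The genuine positions of X and Y there cannot be separated from displaced ones without the sequences, so no coordinate was moved. No biological explanation was tested.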

How the results depend on the processing

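With 18 results and 87 alternative values, 36 stayed within the interval or within 1.5 times of the reported value. The settings with regions of shared reads kept, or with chromosomes 1, X and Y added, were chosen after seeing the data, and adding those chromosomes, run for the counts of regions and the shares found in another library, moved none of these. Thinning to the smallest depth, run for the same results, and 1 bp of overlap, run for the shares, also moved none. The thinning took F only to 92.4% of its depth and left HNF4gamma as it was. It also drew each window separately, although neighbouring windows share reads, so it is a weak check on depth. At an adjusted p of 1e-10 the regions numbered 8625 (F), 5956 (AB) and 221 (HNF4gamma), and at 0.01 HNF4gamma had 1981. Keeping shared reads gave 1316 HNF4gamma regions. By construction a higher threshold leaves fewer regions. Shares of regions found in another library, in percent, moved as follows. With summits within 50 bp they were 41.9% (F in AB), 1.92% (F in HNF4gamma), 57.3% (AB in F), 2.63% (AB in HNF4gamma), 37.9% (HNF4gamma in F), 38% (HNF4gamma in AB). At 0.01 in the library searched they were 73.4% (F in AB), 6.11% (F in HNF4gamma), 89.7% (AB in F), 8.28% (AB in HNF4gamma), 73.3% (HNF4gamma in F), 72.9% (HNF4gamma in AB). With shared reads kept they were 64.5% (F in AB), 6.15% (F in HNF4gamma), 85.4% (AB in F), 7.98% (AB in HNF4gamma), 75.9% (HNF4gamma in F), 74.4% (HNF4gamma in AB). At 1e-10 in both libraries they were 1.39% (F in HNF4gamma), 88.5% (AB in F), 2.22% (AB in HNF4gamma), 54.3% (HNF4gamma in F), 59.7% (HNF4gamma in AB). Numbers of regions that differed moved too. Scaled by background depth they were 14 (F over AB), 6423 (F over HNF4gamma), 1 (HNF4gamma over F), 3791 (AB over HNF4gamma), 2 (HNF4gamma over AB). With shared reads kept they were 2 (F over AB), 19 (AB over F), 886 (F over HNF4gamma), 850 (HNF4gamma over F), 699 (AB over HNF4gamma), 481 (HNF4gamma over AB). Scaled by the median ratio they were 953 (F over HNF4gamma), 671 (AB over HNF4gamma), 67 (HNF4gamma over AB). With at least 20 reads over the pair they were 228 (F over HNF4gamma), 159 (AB over HNF4gamma), 373 (HNF4gamma over AB). Listed positions in the merged regions of all libraries were 51.9% (F), 48.9% (AB) and 11.2% (HNF4gamma), and with shared reads kept in own regions 77.6%, 76.8% and 63.7%. These moves were judged against the Wilson intervals, which are too narrow. Apart from the effects of construction named here, the cause was not tested. Depth limits weak sites in each library, as simulated sites at 5 times the background were recovered in 10.5% (F), 16.4% (AB) and 7.39% (HNF4gamma) of cases. No paired analysis was possible because each antibody has 1 library. Not run were the alternatives on duplicates, fragment shift, local background and placement of reads, because scores hold no reads or strands, and those on annotation, gene lists and motifs, because a genome and annotation of the matching build were not used here.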

Other observations

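HNF4alpha regions lay close to one another. Another F region was found within 10 kb for 39.5% of F regions (exact 95% interval 38.7 to 40.3), against a mean of 12.1% and at most 12.96% in 100 sets of random positions with the same number per chromosome. For AB the share was 35.1% (34.2 to 36.1) against 9.06%. The random positions were spread evenly over each chromosome, empty stretches included, and runs of weak regions were not left out. The excess is thus not a measure of clustered binding alone. The megabases with the most regions called with both antibodies, chosen after their values were seen, were 48 to 49 Mb on chromosome 17 with 30 regions, 41 to 42 Mb on chromosome 17 and 10 to 11 Mb on chromosome 21 with 28 each, 57 to 58 Mb on chromosome 16 with 27 and 114 to 115 Mb on chromosome 10 with 26, against a mean of 3.41. The one on chromosome 21 stood apart, as its highest F count was 23 reads and 27 of its 28 regions were listed in the HNF4gamma library. The other 4 reached 62 to 192 F reads and had 4 to 9 regions listed there.

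In the tests below, the one of listed positions against shifted places, the one of the step in F regions on chromosome 14 and the allowance for PCR copies were chosen after the result was seen. HNF4gamma regions at weak HNF4alpha regions may be background places that are high in every library, since 86.8% of them had another HNF4gamma region within 100 kb, and those at no HNF4alpha region were similarly crowded (72.9%). Regions under 26 reads that recur elsewhere with the same counts were not all removed, and may be among them. For those at F regions of at least 40 reads this share was 19.2%, with an interval that includes the bound of 20% set for the test, so background there, such as easily sheared open chromatin, cannot be told apart from binding without an input library. Chance overlap of listed positions is argued against by the 73.6% of the strongest F regions that were listed. Cross-reaction of the antibody with HNF4alpha at 1 constant proportion cannot be told apart from HNF4gamma binding. Around the best proportion (7.27% of F reads), HNF4gamma reads at 189 F regions of at least 100 reads deviated by 1.68 times the Poisson variance, with 34 unlisted regions at 6 reads, against 0.913 to 1.32 for AB reads thinned to the same total. That bound, set beforehand, leaves out what is peculiar to the HNF4gamma library, as thinning breaks up PCR copies and shrinks uneven background. The HNF4gamma windows held 1.13 reads per listed position, an upper estimate of copies at which the bound would be 1.67, about the value seen (1.67 without the highest region), and uneven background is not covered by it.

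The uneven background of the HNF4gamma library is in line with extra copies of chromosomes or chromosome segments in this cell line. On chromosome 14 it fell from 49.8 regions per Mb between 20 and 45 Mb to 0.21 above, and the listed regions away from called regions in the other libraries stepped at the same place, by 13.7 times in F and 23.4 times in AB. Density of HNF4alpha regions as the cause is argued against there, as the step of the background was 74.8 times that of the F regions, although over the 16 chromosomes outside the 5 densest the background followed F regions per Mb (Spearman rho = 0.78). For whole chromosomes, 87.3% of the pieces of the 5 densest lay above the median of the others (79.6 to 92.9), with the preset bound of 80% inside the interval. The 5 were picked by this same background, so a high share was partly built in, and neighbouring pieces are not independent. The test therefore cannot decide the question. The median piece held 10.4 regions per Mb on chromosome 2, 10.9 on 16, 12.1 on 17 and 12.4 on 20. It held 0.3 on chromosome 14, against 2.4 over the other chromosomes. Chromosomes 14 and 17 changed along their length. Since weak regions are called against 1 genome-wide rate, counts of weak regions may differ between such segments for this reason alone.

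Part of what is listed at the start of chromosome 1 had a counterpart elsewhere. Of 371 runs of positions between 0.3 and 5 Mb in F, 40 recurred with the same spacing on chromosome 6 between 30.6 and 33.1 Mb and 5 on chromosome 4. In AB, 2 of 190 recurred on chromosome 6.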
